A study of Caulobacter vibrioides NA1000 with 12 samples.

How the data were processed

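Caulobacter crescentus NA1000 cells were synchronized with a Ludox density step, released as swarmer cells into M2G minimal glucose medium, and sampled at 30 min intervals until division, per the labels' protocols. Cells were treated with 100 µg/mL chloramphenicol for 2 min before harvest, which arrests elongating ribosomes. There were 12 libraries, 6 of RNA-seq and 6 of ribosome profiling, with 1 library per stage and assay. The stages, in order, were swarmer, early stalk, late stalk, early predivisional, late predivisional and post division. RNA-seq libraries came from fragmented RNA depleted of ribosomal RNA, and ribosome profiling libraries from the fragments that ribosomes protect from nuclease. Groups were taken from the sample titles.

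Each deposited RNA-seq file held whole read counts per genome position and strand. Each deposited ribosome profiling file held estimated counts per position and strand, fractional to 1 decimal. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.8. The genome build, the handling of reads with several matches, the trimming and the base of the read that is counted are not given in the sources used here. Estimated counts were summed per gene and rounded to whole numbers before any count test.

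Gene borders, locus tags and symbols came from the RefSeq gene table of assembly ASM2200v1 (NA1000), and no genome sequence was used here. The table was checked against the files: 95.0% of footprints lay inside coding sequences, against 88.5% and 89.5% with the table moved by 30 nt to either side. File positions counted from 0. After 1 was added, RNA read positions peaked at the first coding base, at 3.79 and 3.88 times the median of the other 20 positions on the plus and minus strands. The table gives no strand, so a gene's strand was set to the one that held at least 90% of at least 20 pooled footprints. That assigned 3493 of 3886 coding genes, and the strand with more RNA reads was the same for 96.1% of them. A gene's antisense reads were kept apart. Gene names and neighbours alone are printed from the table, and no coordinates.

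Reads were summed on the coding strand without the first and last 15 nt of each coding sequence, for 3472 genes with at least 60 nt left, of which 647 had a symbol. Positions inside overlapping genes of 1 strand counted for both. Genes with a mean count under 20 per library were left out, which left 3439 genes for mRNA, 3396 for footprints and 3383 for both. Library sizes were scaled by the trimmed mean of M values (TMM), and CPM values are counts relative to these scaled sizes. Translational efficiency is the footprint CPM over the mRNA CPM of the same gene and stage, with a pseudocount of 0.5 added to each count.

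With 1 library per stage, no 2 stages could be compared with replicates. The planned tests were edgeR quasi-likelihood tests of linear and quadratic terms of the stage order, with 3 residual degrees of freedom. They were run on the mRNA libraries, on the footprint libraries, and for efficiency as the interaction of these terms with assay. The threshold was a Benjamini-Hochberg adjusted p of 0.05. The size of change over stages was described by the highest over the lowest value of each gene, beside 100 Poisson simulations of unchanged genes. Agreement of the assays was measured across genes on log2 deviations from each gene's mean over stages. These choices, the topics of 19 gene lists, the members given by symbol and the alternatives were fixed before the data were examined.

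A further edgeR test was added after the trend counts were seen: stage as a factor with assay as a block over all 12 libraries (5 residual degrees of freedom), with 6 contrasts between stages. Its spread is the disagreement of the assays within a stage, not the spread between cultures. The labels do not say whether both libraries of a stage came from 1 culture, so this test compares these libraries and not the stages in general.

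The lists were master regulators, polarity and phosphosignalling, cell division, DNA replication and segregation, flagellar basal body and hook, flagellins, chemotaxis, pili, holdfast and stalk, ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, ATP synthase, NADH dehydrogenase, chaperones and proteases, RNA polymerase and sigma factors, peptidoglycan and cell shape, and S-layer. TonB-dependent receptors were not analysed here, because the gene table has no product names. Lists or members defined by product, among them all ribosomal protein, synthetase and NADH dehydrogenase genes and part of the chemotaxis and pilus lists, were matched by symbol family, and the families were recorded after gene values had been seen. A list of 13 low-oxygen genes was also made after the values were seen. Unless another base is named, list medians are of log2 deviations from each gene's mean over stages, for efficiency too. They are given with their percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries.

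The rule for named genes, for each trend test, took every master regulator, the 8 genes with the largest fitted range among those past the test with a mean count of at least 100, and up to 3 members of every other list past the test, or otherwise the member with the highest mean count. Other genes are named as examples with large differences, and were chosen after their values were seen.

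Libraries held 4404482 to 16708290 reads for ribosome profiling and 2891648 to 9246445 for RNA-seq. Intervals on folds are 95% intervals of counting error only, since no molecular identifiers are described. A count of 0 was set to a floor of 3 counts for bounds. Alternatives were DESeq2 size factors, library totals alone, a DESeq2 likelihood ratio test, limma-voom, count filters, gene regions, other trend terms, a stricter threshold, and leaving out each stage. The tests were checked on simulated counts with 200 changed genes after the first fits had been run. At a 2-fold change the mRNA, footprint, efficiency and stage tests recovered 4, 2, 17 and 60 of 100 genes, and at 8-fold 97, 75, 100 and 100. The simulated trends had the linear and quadratic shape that the trend tests fit, and all genes shared 1 dispersion. Recovery of changes of other shapes by the trend tests was not measured. In the data, 290 genes in mRNA and 443 in footprints spanned 8-fold or more, while 47 and 4 genes were called. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.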

Results

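Ribosome profiling and RNA-seq were collected over 6 stages of the Caulobacter cell cycle, from the motile swarmer cell through the stalked and predivisional cell to the cells just after division. The question of the design was how mRNA levels and translation vary during this asymmetric cycle. In stage order, the RNA-seq libraries held 9246445, 6606849, 2891648, 3854050, 4777133 and 7502223 reads. The ribosome profiling libraries held 10291641, 16708290, 8080138, 5753383, 7943615 and 4404482 reads. Each value below comes from 1 library per stage and assay, so no difference between stages has a replicate check. Intervals on folds of single genes cover counting error only. Intervals on medians, spreads, ratios and coefficients over genes come from resampled genes, which are not independent replicates. As the synchronization is confounded with the swarmer libraries, no difference from swarmer cells can be assigned to the stage alone.

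The mRNA of the master regulators of the cycle had its highest value at a stage that depended on the gene. The mRNA of ctrA (CCNA_03130), the response regulator that represses replication initiation and activates motility genes, rose from 150.3 CPM in swarmer to 2796 CPM in early predivisional cells, 18.6-fold (17.5 to 19.8; edgeR adjusted p 0.0248). gcrA (CCNA_02328), the regulator active after replication starts, was highest in early stalk cells at 1730 CPM, 5.81-fold (5.42 to 6.24) above early predivisional cells. ccrM (CCNA_00382), the DNA methyltransferase, stood at 21.3 CPM in swarmer and 597 CPM in late predivisional cells, a 28.1-fold span (adjusted p 0.285). sciP (CCNA_00948), an inhibitor of CtrA-dependent transcription, was at 975 CPM in late predivisional and 65.8 CPM in late stalk cells. dnaA (CCNA_00008), the replication initiator, was at 2021 CPM in swarmer and 932 CPM in early predivisional cells. The related regulators mucR1 and mucR2 spanned 1.52-fold and 1.95-fold. Of these genes ctrA alone passed the mRNA trend test, over all genes and when adjusted over the list alone.

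**Figure D1:**
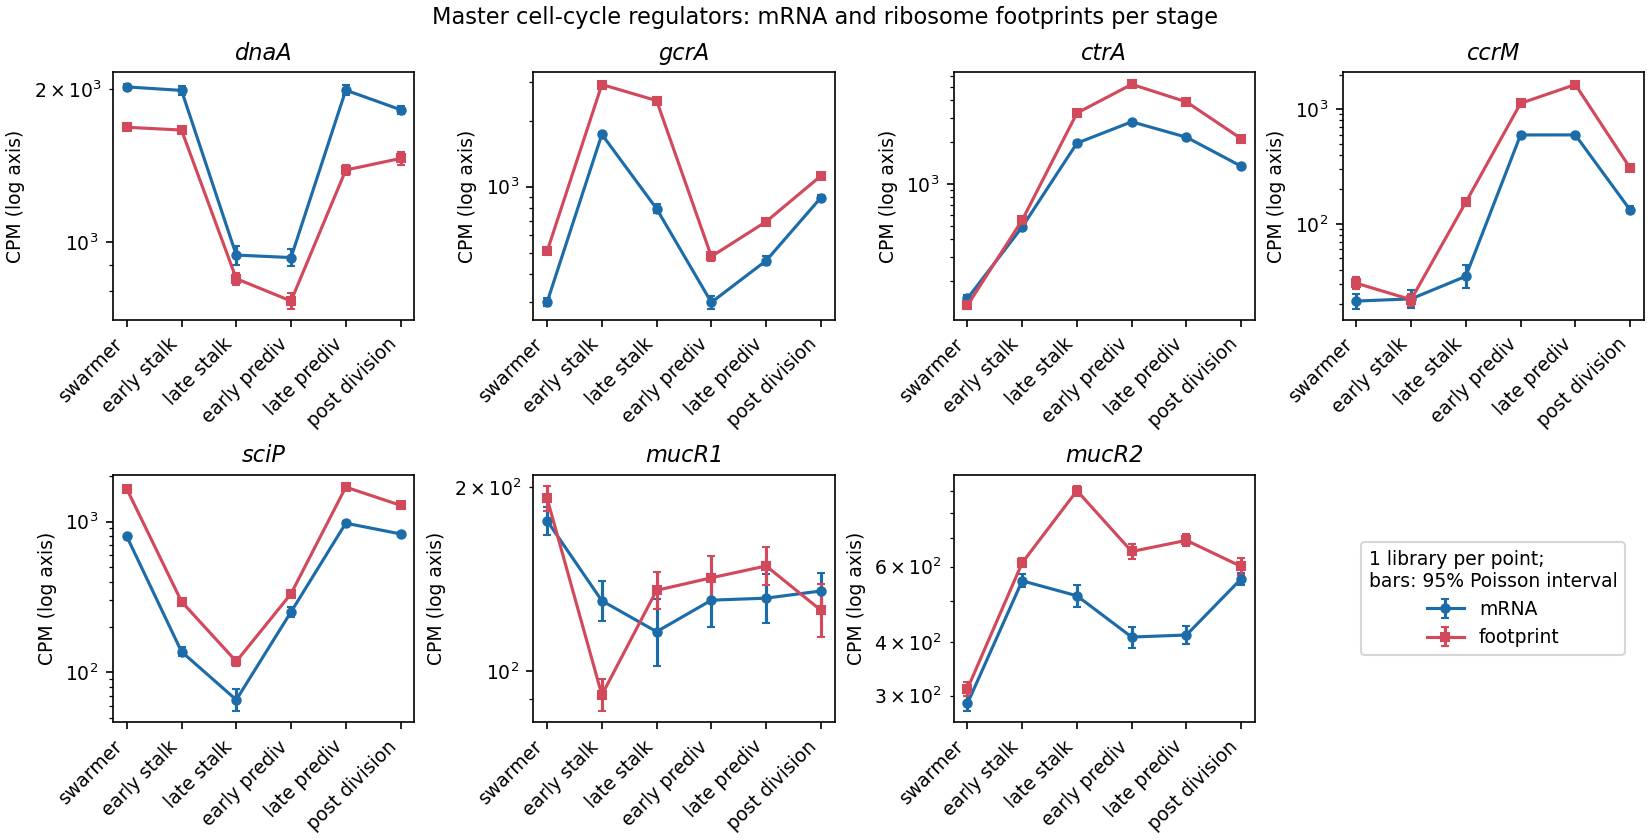
CPM on a log axis for 7 master regulators over the 6 stages, with mRNA as circles and ribosome footprints as squares, 1 library per point, and bars for the 95% Poisson interval of the count. ctrA climbs 18.6-fold in mRNA and 38.7-fold in footprints from swarmer to early predivisional cells, while gcrA is highest in early stalk cells.

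Over all genes, 47 of 3439 changed along the stage order in mRNA (edgeR quasi-likelihood trend test, adjusted p below 0.05; 616 at unadjusted p below 0.05). The fitted peak was in swarmer cells for all of them except ctrA in early predivisional cells and CCNA_01587, CCNA_01585, CCNA_03022, CCNA_03158 and CCNA_03159 in post-division cells. Swarmer peaks cannot be told apart from an effect of the synchronization. The lowest p belonged to CCNA_03624, which fell from 4980 CPM in swarmer to 57.7 CPM in post-division cells, 86.3-fold (77.7 to 96.2; adjusted p 0.00315). staR (CCNA_02334), a transcription regulator of stalk growth, and spmX (CCNA_02255), which brings the kinase DivJ to the stalked pole, fell 29.7-fold and 34.3-fold from swarmer to early predivisional cells (adjusted p 0.0190 and 0.0258). The bactofilin gene bacB (CCNA_03117) fell 14.7-fold (12.9 to 16.7; adjusted p 0.0123) and rpoH (CCNA_03195), the heat shock sigma factor, 5.26-fold (adjusted p 0.0321) between the same stages. The 8 called genes with the largest fitted range included the cbb3 oxidase genes ccoN, ccoO, ccoQ and ccoP, with ccoN at 2013 CPM in swarmer and 20.5 CPM in post-division cells, and ftrB, CCNA_02604 and CCNA_03940, all highest in swarmer cells. The count depended on the setting: DESeq2 called 462 genes, limma-voom 20, and edgeR 88 without the early stalk and 2 without the late predivisional library. No gene passed edgeR without the swarmer, late stalk or early predivisional library, where 404, 403 and 347 had an unadjusted p below 0.05. Many genes with large ranges, ftsZ and ccrM among them, did not pass, and 1634 of 3439 genes (47.5%) spanned 2-fold or more. Counting error alone gave a mean of 24.2 such genes in Poisson simulations, which leave out any spread between libraries or cultures, here and for the other measures, so an excess over them does not show an effect of stage.

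Most motility genes had their highest mRNA in predivisional cells. The median mRNA of 28 flagellar basal body and hook genes lay -1.93 (log2) from the genes' own mean over stages in early stalk cells and 2.30 in early predivisional cells, at percentiles 0 and 100 of random lists. flgE (CCNA_00947), the hook protein, was at 19.3 CPM in swarmer and 1341 CPM in early predivisional cells, 69.4-fold (59.2 to 82.0), and flgD, which is needed for hook assembly, spanned 43.2-fold (31.0 to 62.1). Pilus genes had medians of -1.69 in early stalk and 2.13 in early predivisional cells, with cpaC, the secretin of the pilus, spanning 31.4-fold, while pilA, the pilin itself, was highest in swarmer cells at 2818 CPM and lowest in late stalk cells at 271 CPM. Chemotaxis genes peaked in late predivisional cells (median 1.60 against -1.49 in early stalk), where the kinase gene cheAI stood 13.7-fold above early stalk. Flagellin genes peaked there too (median 1.55 against -2.05 in late stalk), although fljJ was highest in early predivisional cells at 866 CPM and fljN in swarmer cells at 1001 CPM. Holdfast and stalk genes had a median of 1.13 in late predivisional cells, with hfaA, for holdfast attachment, highest there at 308 CPM and stpA, a stalk barrier protein, highest in late stalk cells at 626 CPM. In the mRNA trend test by edgeR over all genes, bacB was the only member of these lists to pass, with 1 flagellar and 1 holdfast gene past it when adjusted over the list alone.

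**Figure D2:**
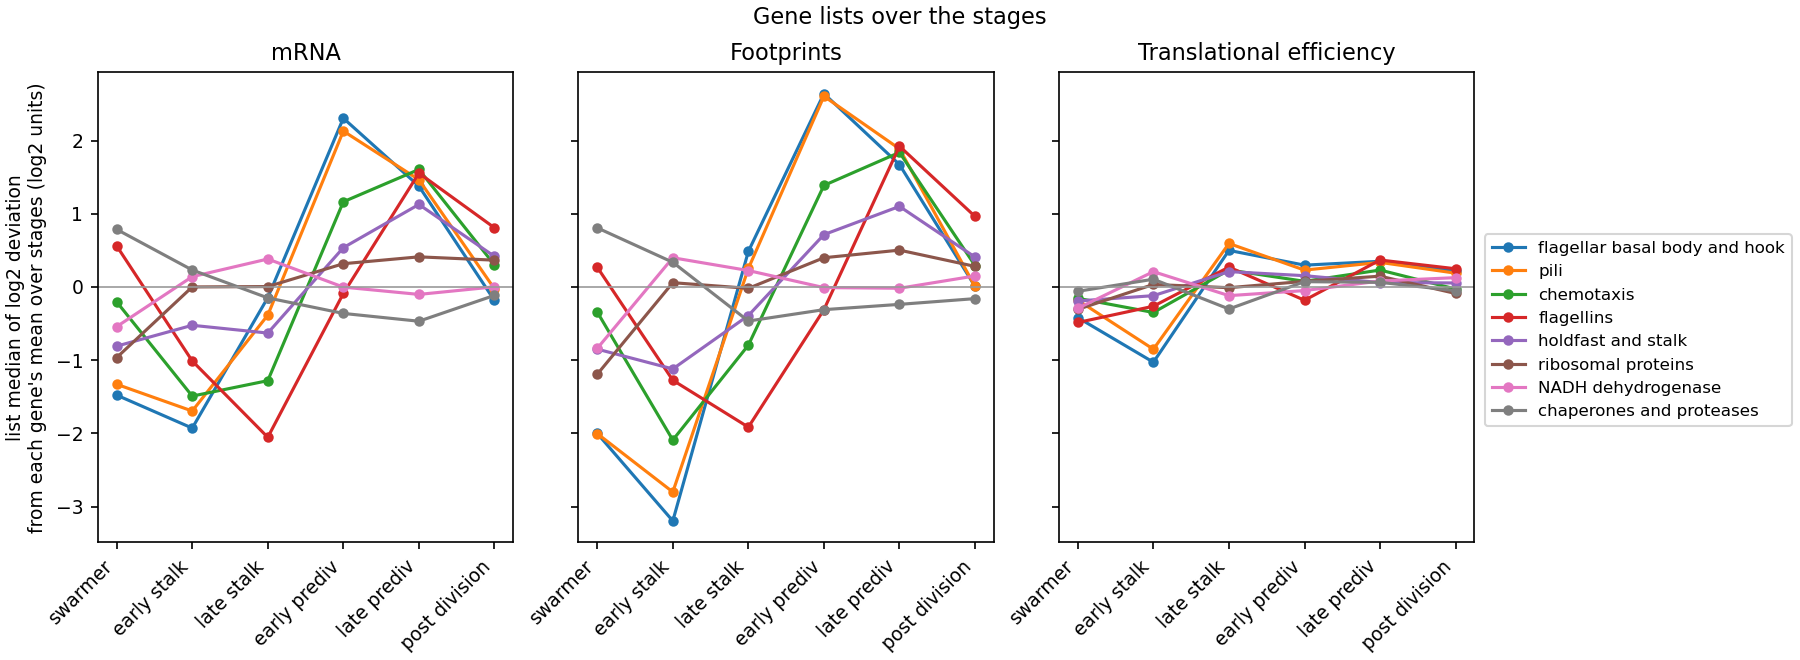
Median log2 deviation from each gene's mean over the stages for 8 gene lists, in mRNA, footprints and translational efficiency, 1 library per stage and assay. Flagellar and pilus genes run from -1.93 and -1.69 in early stalk cells to 2.30 and 2.13 in early predivisional cells in mRNA.

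Several division and shape genes had their lowest mRNA in swarmer cells. ftsZ (CCNA_02623), the division tubulin homologue, was at 144 CPM in swarmer and 4407 CPM in late stalk cells, 30.7-fold (28.9 to 32.6; edgeR adjusted p 0.593). mipZ (CCNA_02246), which places the division site, was 16.1-fold higher in early stalk than in swarmer cells, and ftsK, the DNA translocase, 10.3-fold higher in early predivisional than in early stalk cells. The median of the 20 cell division genes was -0.49 in swarmer and 0.17 in late predivisional cells. In the peptidoglycan and shape list (median -0.44 in swarmer), creS (crescentin) spanned 5.99-fold and murD 5.05-fold, both lowest in swarmer, while mreB spanned 1.19-fold. Of the polarity genes (median -0.42 in late stalk, percentile 0), staR and spmX passed the mRNA test over all genes and 3 passed it when adjusted over the list alone. tacA, a regulator of stalk genes, was highest in late predivisional cells, 22.7-fold above early stalk. Replication genes had a median of 0.16 in early stalk cells, where the ribonucleotide reductase genes nrdB and nrdJ and the primase gene dnaG were highest, 4.04-fold, 3.09-fold and 3.84-fold above early predivisional cells. No division, shape or replication gene passed the mRNA trend test, over all genes or adjusted over the list alone.

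Ribosomal protein genes on 1 side, and chaperone and protease genes on the other, were displaced in opposite directions in the swarmer library. The median mRNA of 26 ribosomal protein genes was -0.96 in swarmer cells (percentile 0) and 0.41 in late predivisional cells; rplB spanned 4.09-fold (3.97 to 4.20) and rpsE 1.91-fold, both lowest in swarmer. None passed over all genes and 13 passed when adjusted over the list alone. Chaperone and protease genes had a median of 0.79 in swarmer cells (percentile 99.8): dnaK was at 2366 CPM there and 1158 CPM in late predivisional cells, and clpB and dnaJ spanned 3.60-fold and 3.27-fold, with 5 of 7 past the test when adjusted over the list alone and none over all genes. NADH dehydrogenase genes had medians of -0.54 in swarmer and 0.38 in late stalk cells, none past the mRNA test either way. In post-division cells the mRNA medians were 0.37 for ribosomal protein, -0.12 for chaperone and protease and 0.002 for NADH dehydrogenase genes. The design confounds the synchronization with the swarmer libraries, so these swarmer values cannot be assigned to the stage alone. The ATP synthase gene atpD spanned 3.93-fold and atpA 2.45-fold, both lowest in swarmer, with 1 past the test when adjusted over the list alone. Of the RNA polymerase and sigma factor genes, rpoH alone passed over all genes and 2 passed when adjusted over the list alone; the list median was -0.49 in swarmer. The surface layer protein gene rsaA was the most abundant of its list, at 43259 CPM in swarmer and 62326 CPM in late predivisional cells, and the list median lay between -0.26 and 0.24. The synthetase list lay between -0.14 and 0.19, with ileS spanning 1.39-fold, and the 1 translation factor with counts, lepA, spanned 1.48-fold. No surface layer, synthetase or translation factor gene passed the mRNA test either way.

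Footprints, which measure ribosomes on each mRNA, had a median range of 2.03-fold per gene against 1.94-fold for mRNA. ctrA footprints were at 134 CPM in swarmer and 5199 CPM in early predivisional cells, 38.7-fold (36.5 to 41.1; edgeR adjusted p 0.0673), and ccrM footprints spanned 74.9-fold (66.2 to 85.1). The 4 of 3396 genes that changed along the stage order (edgeR; 771 at unadjusted p below 0.05) were all highest in swarmer cells: CCNA_03624 (170-fold, adjusted p 0.0336), bacB (22.4-fold, 0.0377), CCNA_01361 (11.1-fold, 0.0336) and CCNA_03400 (7.26-fold, 0.0426). The flagellar median ran from -3.20 in early stalk to 2.64 in early predivisional cells, the pilus median from -2.80 to 2.60, and the ribosomal protein median from -1.19 in swarmer to 0.50 in late predivisional cells. sciP footprints were 14.3-fold and gcrA footprints 6.06-fold higher at their highest than at their lowest stage, dnaA 2.20-fold, mucR1 2.10-fold and mucR2 2.90-fold. When adjusted over the list alone, footprint trends passed for 15 ribosomal protein genes, 4 chaperone or protease genes, 2 polarity genes, both ATP synthase genes, and 1 gene each of the master regulators, the holdfast and stalk list and the sigma factor list, and for no gene of the other fixed lists. Footprints of 1746 of 3396 genes (51.4%) spanned 2-fold or more (33.6 from counting error alone). The trend count moved with the setting: DESeq2 called 707 genes, library totals alone 57, limma-voom 0 (762 at unadjusted p below 0.05), and edgeR 324 without the early stalk library and 114 without the swarmer library. Leaving out any other stage gave 0 by edgeR, with 498 to 860 genes at unadjusted p below 0.05.

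Translational efficiency had a median range of 1.69-fold per gene over the stages. ctrA had 2.08-fold higher efficiency in early predivisional than in swarmer cells (edgeR trend p 0.00515, adjusted p 0.368), and ccrM 4.47-fold higher in late stalk than in early stalk cells. Flagellar and pilus genes had their lowest efficiency in early stalk cells. Their median log2 deviations from each gene's mean efficiency over stages were -1.03 and -0.85 there and -0.42 and -0.18 in swarmer cells. The medians were 0.50 and 0.59 in late stalk and 0.30 and 0.23 in early predivisional cells. In late predivisional and post-division cells they were 0.35 and 0.34, and 0.22 and 0.19. The late stalk and early predivisional RNA-seq libraries also stood apart in RNase P RNA (2.04 and 1.68% of reads, against 0.788 to 0.826% in the other RNA-seq libraries). Taking the median antisense density of each library from the mRNA counts turned the median early predivisional minus early stalk difference of both lists from 1.10 to -0.35 log2 units, with 17 of 42 genes higher in place of 41, while the 10th percentile, chosen after this was seen, left 0.66 with 38 genes higher. For the pilus gene cpaB the efficiency was 10.2-fold higher in late stalk than in early stalk cells, for the flagellin gene fljL 7.70-fold, for rpoN, the sigma factor of late flagellar genes, 5.90-fold higher in late predivisional than in early stalk cells. gcrA spanned 2.47-fold, with its highest efficiency in late stalk cells, and dnaA 1.29-fold, mucR1 1.66-fold, mucR2 1.65-fold and sciP 1.63-fold. Of 3383 genes, 0 passed the edgeR efficiency trend test, 286 had an unadjusted p below 0.05, DESeq2 called 37 and limma-voom 0 (301 at unadjusted p below 0.05). With edgeR's p adjusted over the list alone, 3 flagellar genes and 1 master regulator passed and no gene of any other fixed list. Without the early stalk library edgeR called 89 genes. A range of 2-fold or more was seen for 1072 genes (31.7%; 93.7 from counting error alone).

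Changes in footprints tracked changes in mRNA across genes. Over 3383 genes and 6 stages, log2 deviations of the assays had a Pearson r of 0.837 (0.825 to 0.848 from resampled genes) with a slope of 1.02 footprints on mRNA; this is a correlation across genes, which are not independent replicates. By stage, r was highest in swarmer cells at 0.937 and lowest in late stalk cells, the shallowest RNA-seq library, at 0.624. Each of the 6 libraries of either assay correlated best with its own stage in the other, and mismatched stages gave a mean of -0.135 (-0.668 to 0.616). All 47 genes with a called mRNA trend had a fitted footprint trend in the same direction, and 2 of them, CCNA_03624 and bacB, were called in both tests, where 0.0556 would be shared by independent lists. At unadjusted p below 0.05, 476 genes were shared against 138 for independent lists, 474 of them in the same direction. Efficiency differed more between genes than between stages: the 5th to 95th percentile of genes spanned a mean of 3.03 log2 units (2.93 to 3.14), or 8.18-fold, and the SD was 0.906 between genes and 0.396 within a gene over stages. pilA was among the efficiently translated, at 1.60 (log2) in swarmer cells, with atpA at 1.02, while cpaB was at -2.14 and rpoN at -2.14 in the same stage. However, pilA, cpaB and rpoN also moved with stage. pilA was at 0.32 in early predivisional, cpaB at 0.35 in late stalk and rpoN at -0.38 in late predivisional cells.

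Stage by stage, the swarmer libraries stood furthest from their neighbours. Because the synchronization is confounded with the swarmer libraries, these differences cannot be assigned to the stage alone. Between swarmer and early stalk cells, with both assays together, ftsZ was higher by 4.64 log2 units (SE 0.16), mipZ by 4.21 (SE 0.17) and stpA by 3.69 (SE 0.22). Over the same step bacB was at -2.15 (SE 0.20), tacA at -2.12 (SE 0.20) and spmX at -1.91 (SE 0.40), and sciP was at 0.176 times its swarmer level. Of the ribosomal protein genes, 22 of 26 were higher in early stalk cells and none lower, as were 11 of 14 NADH dehydrogenase genes, and 4 of 7 chaperone and protease genes were lower and 1 higher. From early to late stalk, 23 of 28 flagellar genes and 10 of 14 pilus genes were higher (pilA was lower), and ctrA was higher by 2.27 (SE 0.26). From late stalk to early predivisional cells, 22 flagellar, 12 pilus, 11 of 12 chemotaxis and 9 of 17 holdfast and stalk genes were higher (5 of the latter were lower), with flgE at 3.74 (SE 0.43) and ccrM at 3.32 (SE 0.42). From early to late predivisional cells 4 of 6 flagellin genes were higher, fljM by 2.76 (SE 0.21), as was pilA by 2.78 (SE 0.31). After division, 17 flagellar, 11 pilus and 10 chemotaxis genes were lower than in late predivisional cells. This edgeR test, added after the trend counts were seen, takes the assays of a stage as its spread, so it compares these libraries only.

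**Figure D3:**
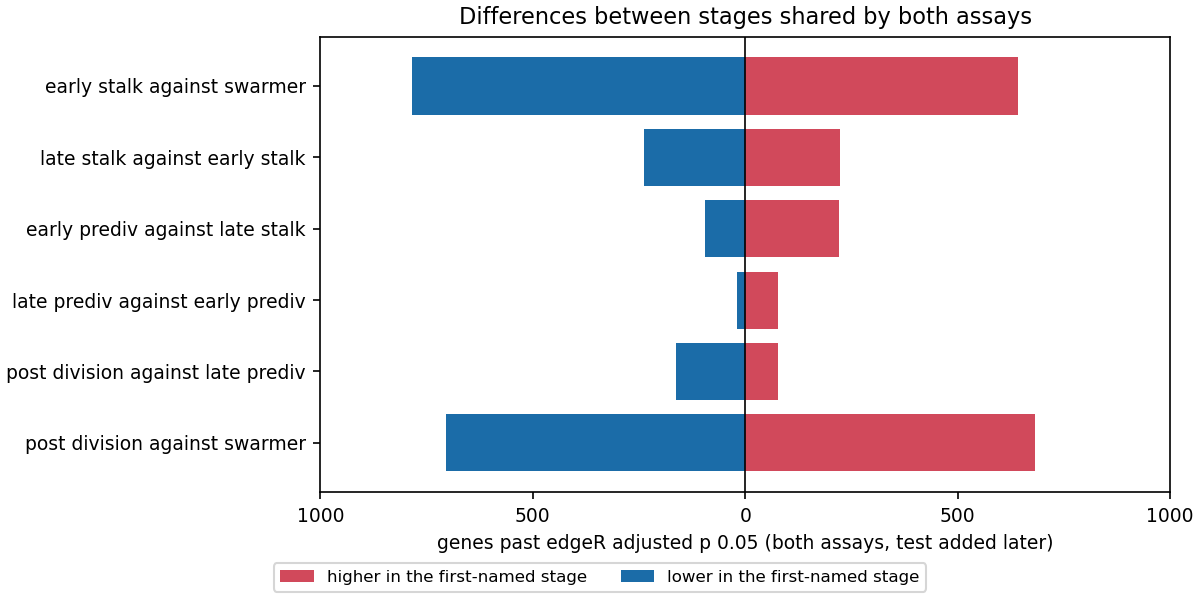
Genes past an edgeR adjusted p of 0.05 in each of 6 contrasts between stages over both assays, drawn as counts to the right where higher and to the left where lower in the first-named stage. Early stalk against swarmer has 643 higher and 784 lower genes, and late against early predivisional cells 76 higher and 19 lower.

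In that test 1763 of 3383 genes (52.1%) differed among the stages, and 793 without the swarmer libraries. Among the genes called, 705 were highest in swarmer cells, 236 in early stalk, 300 in late stalk, 187 in early predivisional, 263 in late predivisional and 72 in post-division cells. By list, it called 27 of 28 flagellar genes (25 highest in early predivisional cells), 11 of 12 chemotaxis genes (10 highest in late predivisional cells), all 14 pilus, 6 flagellin, 17 holdfast and stalk and 24 polarity genes, 6 of 7 master regulators (7 when adjusted over the list alone) and 24 of 26 ribosomal protein genes. It also called 11 of 20 division, 9 of 12 replication, 11 of 14 NADH dehydrogenase, 6 of 7 chaperone and protease, 4 of 7 sigma factor or polymerase, 4 of 6 shape, 2 of 2 ATP synthase, 1 of 3 surface layer and 1 of 6 synthetase genes, and not lepA. When adjusted over the list alone, it called 13 NADH dehydrogenase, 7 chaperone and protease, 5 sigma factor or polymerase and 0 surface layer genes, with the other counts unchanged apart from the master regulators. In stage order, the 5 neighbouring contrasts called 1427 genes (643 higher, 784 lower), 462 (223 and 239), 315 (221 and 94), 95 (76 and 19) and 241 (77 and 164), and post division against swarmer called 1387 (682 and 705). With library totals alone the median gene moved to -0.26 in early stalk against swarmer and to -0.25 in post division against swarmer, and the splits became 481 higher and 993 lower, and 515 and 960. Post division against swarmer turned to more genes higher than lower with DESeq2 size factors (767 and 643), the DESeq2 test (788 and 652) and a mean count of 100 (710 and 615), and late against early stalk with DESeq2 size factors (234 and 227), library totals (227 and 205) and the DESeq2 test (311 and 273). Neither split therefore has a settled direction. Library totals gave 49 higher and 24 lower for late against early predivisional cells, and 90 and 124 for post division against late predivisional cells. The DESeq2 test called 186 genes for late against early predivisional cells (133 higher, 53 lower).

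The genes of low-oxygen respiration, except fixK in mRNA, were highest in the swarmer libraries of both assays. The list, made after the values were seen and so no independent evidence of its own direction, had a median of 4.15 (log2) in swarmer mRNA and 6.00 in swarmer footprints, and -1.31 and -1.29 in post-division cells. cydA and cydB, the subunits of the bd oxidase, were at 3602 and 2579 CPM in swarmer mRNA and 44.0-fold and 35.0-fold above their lowest stages. hemN, for haem synthesis without oxygen, and fixG spanned 51.4-fold and 54.1-fold. fixK mRNA was highest in late predivisional cells at 34.3 CPM (stage test adjusted p 0.114). The mRNA trend test called 10 of the 13 genes over all genes and 12 when adjusted over the list alone, the footprint test 0 and 12, the efficiency test 0 and 1, and the added stage test 12. As log2 deviation from each gene's mean efficiency over stages, the list median was 1.82 in swarmer and -1.47 in early stalk cells. The early stalk value lay further down than those of the flagellar and pilus genes. Values outside swarmer can rest on few reads: ccoQ and ftrB had the same log2 efficiency of -3.06 in late stalk cells. Low counts and background reads were not checked for this list.

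**Figure D4:**
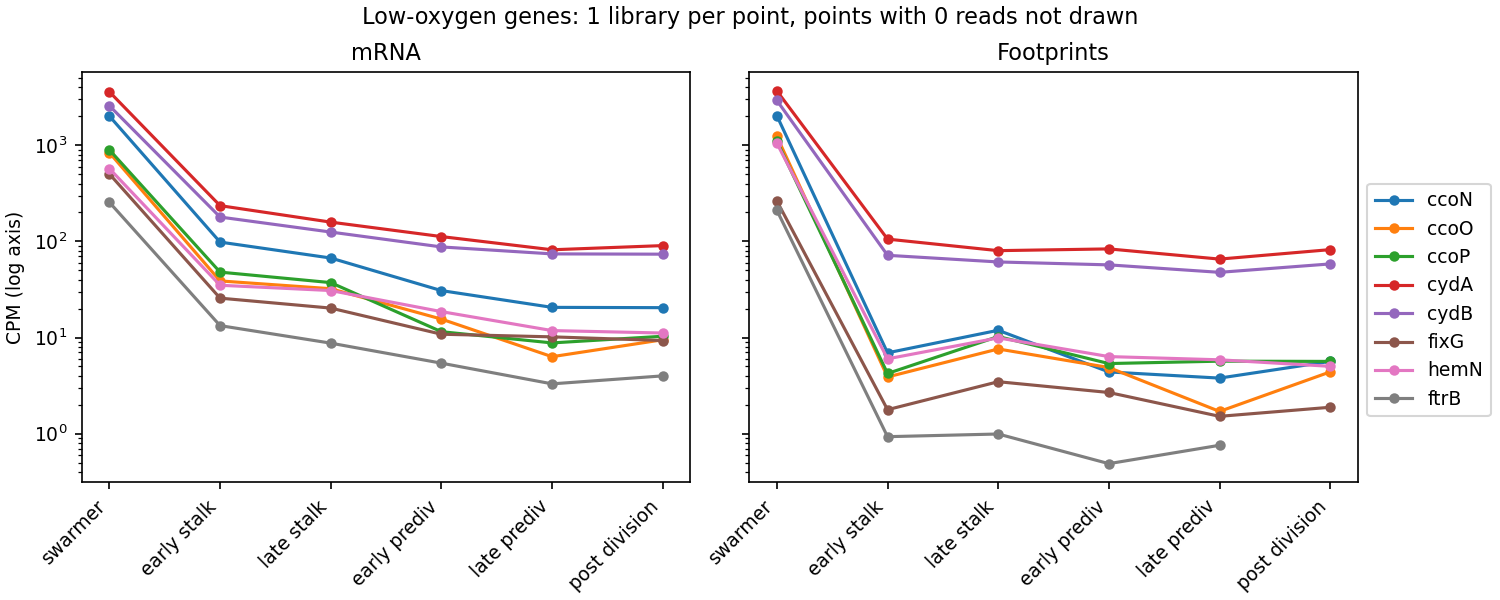
CPM on a log axis for 8 low-oxygen genes over the 6 stages in mRNA and footprints, 1 library per point, with values of 0 reads left out. ccoN stands at 2013 CPM of mRNA in swarmer cells and 20.5 CPM in post-division cells.

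Along coding sequences, reads of both assays were denser near the start. Over 2041 genes, the median ratio of density in the first 50 codons to the rest was 1.84 in the swarmer and 1.59 in the post-division library, with a mean over the 6 stages of 1.68. The same ratio in the RNA-seq libraries, as background, ranged from 1.47 in swarmer to 1.61 in post-division cells, with a mean of 1.54. Over the first 100 codons the order turned, with a mean of 1.42 for footprints and values of 1.39 to 1.61 over the RNA-seq libraries, whose mean was higher. The late stalk and early predivisional RNA-seq libraries were lowest there (1.39 and 1.41, against 1.48 to 1.61 in the others). Over the first 50 codons both were at 1.48 and did not stand apart from swarmer.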

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

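The tests of genomic DNA in the RNA libraries and of other orders of the stages were chosen after the result was seen, and the test of wrong-strand reads before.

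Several classes of reads outside the coding strand of coding genes stood above the limit of 3 counts. Ribosomal RNA did not in the ribosome profiling libraries, with 0 reads in each, and had 1 to 12 reads in the RNA-seq libraries. These counts need not be what was sequenced, since the handling of reads with several matches is not given. All shares here are of the reads in the deposited counts. Antisense reads within coding sequences made up a median of 4.37% of the RNA-seq libraries (3.58 to 4.61%) and 0.173% of the ribosome profiling libraries (0.157 to 0.293%). Gene strands were set from the pooled footprints, and genes whose footprints were too evenly split between strands were left out. That selection holds the ribosome profiling share down by construction, so the antisense shares of the assays cannot be compared. tmRNA, which frees stalled ribosomes, took 2.57% of RNA-seq and 2.11% of ribosome profiling reads (medians). SRP RNA took 2.76% and RNase P RNA 0.824% of RNA-seq reads, and tRNA 0.299% of ribosome profiling reads. The late stalk and early predivisional RNA-seq libraries stood apart from the other RNA-seq libraries in tmRNA (4.96 and 3.67%, against 2.15 to 2.62%), RNase P RNA (2.04 and 1.68%, against 0.788 to 0.826%), tRNA (1.02% in both, against 0.477 to 0.717%) and the remaining noncoding RNA (2.99 and 2.90%, against 3.83 to 4.15%). No cause of this was tested. The highest limit that a count of 0 allowed in any library was 0.000104% for RNA-seq.

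Antisense RNA reads could come from genomic DNA or from sense reads assigned to the wrong strand. Genomic DNA would give an even density over genes, but the 90th over the 10th percentile of antisense density was 7.05 (6.52 to 7.51), which argues against it as the whole cause. Wrong-strand reads would follow each gene's sense density, but the Spearman coefficient across 3493 genes was 0.0599 (0.0249 to 0.0928), which argues against that too. Antisense transcription stays open as a hypothesis, and no biological explanation was tested.

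The order of the stages was set against other orders of the same libraries. For mRNA, 2 of 100 orders, the true one included, gave at least 47 trend genes, and the highest other order gave 60. For footprints it was 4 of 100 with at least 4 genes, and the highest other gave 336, several times the true count. Read backwards, that order runs from early stalk to post division and then swarmer. As the stages form a cycle, this is the true sequence begun at another stage, and not an unrelated order. A count so far above the true one points to a structure of the samples, whose cause was not tested. Orders that are not this cycle also exceeded the true counts. Early stalk, post division, early predivisional, late predivisional, late stalk and swarmer, in that order, gave 125 footprint genes. Late stalk through post division, followed by early stalk and swarmer, gave 14 footprint genes and the 60 mRNA genes. For efficiency, with 0 genes in the true order, 100 of 100 orders gave as many and the highest other gave 64. By the count of genes at unadjusted p below 0.05, orders as large as the true one numbered 6, 7 and 22 of 100, so on that measure chance was not excluded for any of the 3 tests.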

How the results depend on the processing

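The stage test, its contrasts and their alternatives, the low-oxygen list and the check of list medians with library totals were added after results were seen; all other alternatives named here were fixed before the data were examined. The balance of higher and lower genes turned for post division against swarmer with DESeq2 size factors, the DESeq2 test and a mean count of 100, and for late against early stalk with either scaling and the DESeq2 test. Trend calls depended on tool, terms and stages. With DESeq2, limma-voom, linear terms alone, sine and cosine terms, and an adjusted p of 0.01, the mRNA count of 47 became 462, 20, 0, 76 and 1, and the footprint count of 4 became 707, 0, 0, 76 and 0 (57 with library totals alone). Unadjusted p below 0.05 was held by 397 mRNA and 508 footprint genes with linear terms. Of the sine and cosine calls, 2 mRNA and 0 footprint genes were shared with the main calls. The efficiency count of 0 became 37 with DESeq2 and 7 with sine and cosine terms. Leaving out 1 stage gave 0 to 88 mRNA genes (0 without swarmer, late stalk or early predivisional, 2 without late predivisional, 88 without early stalk), 0 to 324 footprint genes (114 without swarmer, 324 without early stalk, 0 without any other) and 0 to 89 efficiency genes (89 without early stalk, 1 without swarmer, 1 without late predivisional, 2 without post division). The cause was not tested for these 3 counts.

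At 3-fold in place of 2-fold, the range of mRNA over stages took in 895 genes, the range of footprints over stages 1035 and the range of translational efficiency over stages 425, fewer by construction. Leaving out 1 stage gave 1049 to 1585 mRNA and 969 to 1689 footprint genes at 2-fold, the lowest without swarmer. The agreement of the assays was 0.661 by Spearman and 0.874 at a mean count of 100, and ran from 0.756 without swarmer to 0.873 without late stalk. At a mean count of 100 the spread of efficiency was 2.55 log2 units, with low-count genes removed, and 1 chaperone gene passed the mRNA trend test over all genes tested. The footprint start ratio of 1.68 was 1.42 for the first 100 codons and 1.86 for summed reads, and the excess over RNA turned for 100 codons. The stage effect shared by both assays was called for 793 (without swarmer) to 1747 genes with 1 stage left out, 786 of the 793 being among the 1763, and its late against early predivisional contrast 186 with DESeq2. The cause was not tested for the agreement, the start ratio, the range, the stage test or the contrast. Of the other comparisons of main counts or values with an alternative, 274 stayed within 1.5 times or within their interval. Among single named genes, 1287 values kept their side of the threshold, 133 lost a call and 30 gained one. List medians beyond 0.1 kept their sign under DESeq2 size factors. With library totals alone, where either value was beyond 0.1, footprints of the polarity list moved from -0.01 to 0.24 in swarmer and from 0.01 to -0.14 in late predivisional cells, footprints of the shape list from 0.05 to -0.10 in late predivisional cells, and efficiency medians of the master regulator, polarity, synthetase, chaperone and shape lists changed sign in 1 stage each. At a mean count of 100 the efficiency median of the low-oxygen list in late predivisional cells moved from -0.01 to 0.17. Depth limits the late stalk RNA-seq library most, with a median of 148 reads per gene.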

Other observations

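The low-oxygen tests, the copy number test and the stage matching test were chosen after the result was seen; the tests of flagellar efficiency and of mRNAs without a leader were written before, except the background at the 10th percentile.

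Genes outside the fixed lists also differed sharply between neighbouring stages in the added edgeR test, and were picked for their size after the values were seen. From swarmer to early stalk cells dgcA was 32.0-fold and cysH, of sulfate reduction, 21.1-fold higher (SE 0.30 and 0.15 on the log2 scale). From early to late stalk malA and malY were lower, with log2 differences of -4.19 (SE 0.22) and -4.32 (SE 0.35), with their neighbours CCNA_02368 and CCNA_02369 at -4.19 (SE 0.59) and -4.60 (SE 0.67). Over that step CCNA_02274, CCNA_02275 and hutA were higher by 3.97, 3.68 and 3.40 (SE 0.32, 0.27 and 0.71). From early to late predivisional cells hvyA, which keeps swarmer cells free of capsule, was higher by 3.37 (SE 0.46) and hfsJ by 3.00 (SE 0.47). After division znuL was higher by 5.90 (SE 0.90) and the neighbours CCNA_01585, CCNA_01586, CCNA_01587 and CCNA_01588 by 5.57, 5.71, 5.39 and 5.14 (SE 0.75 to 1.05). The edgeR adjusted p of these 5 genes ran from 0.00557 to 0.0120.

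The low-oxygen genes, except fixK in mRNA, were highest in the swarmer libraries, and a candidate explanation is expression in every new swarmer cell. Post-division samples hold new swarmer cells, and there pilA, sciP, perP and fljK stood 2.41 (mRNA) and 2.38 (footprints) log2 units above the early stalk to early predivisional mean. However, pilA was already higher by 2.78 in late than in early predivisional cells (both assays), so its high level was not particular to new swarmer cells. The share of new swarmer cells in these samples was not measured. The low-oxygen list did not return: the higher of its medians was -0.228 (-0.498 to -0.103), against 4.61 and 6.93 in swarmer cells. This argues against expression in every new swarmer cell only so far as such cells made up much of the post-division samples. Conditions before or during the synchronization, such as low oxygen in the culture or gradient, are another candidate for the swarmer level. Post-division height was at most -0.0329 of swarmer height, but the list was made after the values were seen, so this cannot decide. The design confounds these conditions with the swarmer libraries, so they cannot be told apart from any other feature of those samples alone.

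Flagellar and pilus genes had a lower efficiency in early stalk than in early predivisional cells, by a median of 1.10 log2 units (0.82 to 1.57), in 41 of 42 genes. Few footprint counts are argued against: 23 genes with at least 50 early stalk footprints kept 0.731 (0.514 to 0.938) of the difference. Background reads in the RNA libraries were another candidate: with the median antisense density taken from mRNA counts, -0.319 (-1.14 to 0.232) of the difference was left. That subtraction put 14 of 42 genes at the floor, and the 10th percentile as background left 0.596. Antisense density was uneven over genes (90th over 10th percentile 7.05), so 1 density per library need not measure background on the sense strand. The check cannot decide, and background stays open. Regulated translation stays open too, as a hypothesis.

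Stage effects shared by the assays were set against other matchings of footprint to RNA-seq libraries. The true matching gave 1763 genes and was the 1 of 100 matchings with a count as large; the highest other, with early and late predivisional exchanged, gave 1464. This argues against a chance pairing of the footprint and RNA-seq libraries, and does not bear on chance differences between cultures. The test restates that each library correlated best with its own stage in the other assay, so it adds no separate evidence and says nothing of the spread between cultures.

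Genes near the terminus might be lower in mRNA during replication, through gene copy number. The gradient difference between late stalk with early predivisional cells and swarmer cells was -0.23 log2 units (circular-shift permutation p 0.248, two-sided) in mRNA and -0.19 in footprints (p 0.186), so it stays open. Efficiency of 212 genes whose RNA reads start at the first coding base was compared with 3171 others: medians differed by 0.02 log2 units (-0.08 to 0.15; permutation p 0.748, two-sided), so a difference beyond 0.15 is argued against.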
